A study of Nannochloropsis oceanica strain IMET1 with 6 samples.

How the data were processed

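RNA from 3 samples of the insertional mutant HLM23 and 3 samples of the wild type was compared. Per the labels' protocols, 22 ml of each culture was harvested, RNA extraction, library preparation, sequencing, mapping and quantification were carried out by a sequencing company, 1 μg of RNA went into a kit for messenger RNA libraries, and paired-end reads came from an Illumina NovaSeq instrument. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2 with no versions. Settings, strand handling, genome build and annotation are not given in the sources used here.

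The deposited table holds 1 row per gene with coordinates and gene length. Its 6 sample columns hold a signal that the authors made comparable between samples: every value is a whole multiple of 1 step per library within 0.001 of a read, as gene reads divided by a size factor would be. These values are called normalised read counts here. The steps imply totals of 15331673, 16346247 and 18711316 reads in HLM23 replicates 1, 2 and 3, and of 16406373, 16210183 and 16348009 in the WT. The FPKM columns deposited by the authors divide by totals 4 to 7 reads above the sums of the rows, so the 9552 rows hold nearly all reads counted to genes. In 1315 to 1323 genes per library the FPKM used another length than the gene length listed, and FPKM serves here only as a level for the disrupted gene. The log2 fold changes of the authors' deposited comparison were used as an alternative. The p-values and adjusted p-values deposited by the authors were used with them, and the adjusted values equal a Benjamini-Hochberg correction over all rows within rounding. Neither unit corrects for RNA quality, so a gene length trend that differs between libraries would pass into the values. Overlapping genes can share reads, since strand handling is not stated.

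Samples were assigned to strains by their titles. Genes with a mean of at least 1 over the 6 libraries were kept (9452 genes, 100 left out). The test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with 2 groups, all 6 samples, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this scale and understate the change of low genes. The design fixed before the data were examined foresaw a count model, with limma for values that were not raw counts. A count model was not used, because an automatic test of the columns for whole reads did not accept those of HLM23 replicate 3 and WT replicate 3. Their steps lie within 1% of 1, which that test takes for rounding. In all 6 libraries 100% of the values were whole multiples of the step, so the refusal does not speak against whole reads. A count model was thus left out by that rule and not because the values forbid it. On simulated data drawn for this comparison (9432 genes past the filter), the fit recovered 89% of 100 genes changed 2-fold and 98% of 100 genes changed 4-fold, and 5.56% of its calls were unchanged genes. With no changed gene it made 0 calls at the adjusted threshold. The simulation changed 200 genes, none with few reads, whereas 2730 genes were called in the data. It drew libraries independently and gave genes of similar abundance the same spread. These rates may therefore not hold for the data.

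Genes to name were fixed in advance as NO06G03670 and, where the files give no description of any gene, at most 2 genes that rose and 2 that fell, taken as those with the largest fitted change past the threshold, a mean of at least 10 and no overlap between the strains. The 22 gene lists fixed in advance were patterns over gene descriptions. None could be tested, as no description was paired with the IDs used here. The alga grows as single cells of 1 type, so no markers of other cell types were listed.

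The alternatives planned and run were another pseudocount (0.1), no filter, a stricter filter, equal library totals, limma voom, a replicate block, leaving out each library, a stricter threshold and the authors' values. A larger pseudocount, removal of a gene length trend and a fit without the replicate 2 libraries were added after seeing the data.

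To ask whether the replicate 2 libraries held RNA of the other strain or had exchanged labels, genes were chosen from the other 4 libraries, and 4 gene sets were tried in turn. The first took genes with a mean of at least 50 in the other strain and at most 2% of it in their own, the second at most 12.5%. The third took genes past the adjusted threshold with a mean of at least 100 in the other strain and at most 25% of it in their own. The set used took genes past the threshold that changed at least 4-fold, with a mean of at least 100 in the other strain and a lower mean in their own. The first 2 sets were replaced because they held few genes, after their results had been seen. The test for RNA of the other strain was first written before its result and then rewritten with the gene set. The bound first written for exchanged labels, under 5% of genes nearer to the other strain, was met by none of the 4 sets. It was replaced after these results, for a time by 25% and then by an exact 95% binomial interval set against 50%, which an exchange would exceed.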

Results

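Messenger RNA was sequenced in 6 libraries of Nannochloropsis oceanica strain IMET1, a unicellular marine alga known for storing oil, with 3 libraries from the insertional mutant HLM23 and 3 from the wild type (WT). HLM23 carries an insertion that disrupts the gene NO06G03670, described in the literature as coding for an APETALA2-like transcription factor. The series concerns gene targets for raising the lipid content of this alga, and the design asks which transcripts differ between the mutant and the WT under favourable growth. Cultures of 25 ml were started at an optical density of 0.1 at 750 nm, grown at 25 °C under 600 μmol photons per square metre per second with 16 h of light per day, and sampled on day 3, 1 h before dark. The libraries held between 15331673 and 18711316 gene reads each, as implied by the deposited values, spread over 9552 genes on 30 chromosomes. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

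The libraries separated by strain on the first principal component of the log2 values, though not in every pairwise correlation. That component held 62.0% of the variance and placed the HLM23 libraries between -43.6 and -24.8 and the WT libraries between 20.2 and 48.5. Spearman correlations between libraries of the same strain, across genes, ran from 0.969 to 0.988. Between the strains they ran from 0.905 to 0.976, and the highest of these joined HLM23 replicate 2 and WT replicate 2, whose values on the first component, -24.8 and 20.2, lay closest to each other. HLM23 replicate 2 thus correlated slightly more with WT replicate 2 (0.976) than with HLM23 replicate 3 (0.974). Every pair of libraries differed by more than counting noise (chi-square per gene of at least 23.2), so none was treated as a library listed more than once, which does not show whether they came from separate cultures.

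The disrupted gene was still transcribed in HLM23, at about 51.4% of its WT level. NO06G03670 lies on the minus strand of chromosome 6 from 1004518 to 1013731 in the coordinates of the deposited table, whose genome build is not given in the sources used here. Its normalised read count was 1073, 982 and 777 in the HLM23 libraries and 2164, 1664 and 1682 in the WT libraries, or 944 ± 152 (SD, n = 3) against 1837 ± 284 (SD, n = 3). The FPKM was 6.19 ± 1.38 in HLM23 and 12.9 ± 2.32 in the WT (SD, n = 3). The fall was larger than the spread between replicates (log2 fold change -0.96 ± 0.18 SE, limma adjusted p = 0.0026), and all 3 HLM23 libraries lay below all 3 WT libraries. The value is a sum over the whole gene, and the position of the insertion within it is not stated in the labels, so reads from the part before an insertion and from the part after it were not told apart. At 9030 bases it is among the 1891 longest tested genes (3261 bases or more), which stood lower in every HLM23 library than in any WT library (medians of -0.027, -0.0084 and -0.10 against 0.097, 0.030 and 0.060, log2 relative to the mean of all 6), and with a length trend removed from each library its log2 fold change was -0.77.

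Over the whole genome, 2730 of 9452 tested genes (28.9%) differed between the strains at an adjusted p under 0.05 in limma. They divided evenly, with 1374 genes higher and 1356 lower in HLM23. Larger changes leaned towards higher expression in the mutant: 724 genes were at least 2-fold higher and 495 at least 2-fold lower, 156 against 45 changed at least 4-fold, and 24 against 7 changed at least 8-fold. The genes called higher made up 20.2% ± 1.59 of the normalised reads in HLM23 and 10.8% ± 1.39 in the WT (SD, n = 3). Those called lower made up 7.66% ± 1.10 in HLM23 and 14.9% ± 1.87 in the WT, which follows from how they were chosen but gives the size of the shift. The 3 most abundant genes took 7.88% ± 1.25 of the reads in HLM23 and 8.13% ± 1.10 in the WT, a difference smaller than the spread. The even division depended on the scaling: with equal library totals in place of the authors' size factors, the median gene moved to -0.11 on the log2 scale, and 1024 genes were called higher and 1603 lower. At least 2-fold, that scaling gave 578 higher and 661 lower, whereas at least 4-fold it gave 123 against 65 and at least 8-fold 21 against 7. Leaving out HLM23 replicate 1, WT replicate 1 or WT replicate 3 brought the number of calls to 1741, 1527 and 1541. The authors' deposited table puts 3025 genes past an adjusted p of 0.05, of which 1530 were higher and 1495 lower, and 2690 genes were called in both analyses, all in the same direction.

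**Figure D1:**
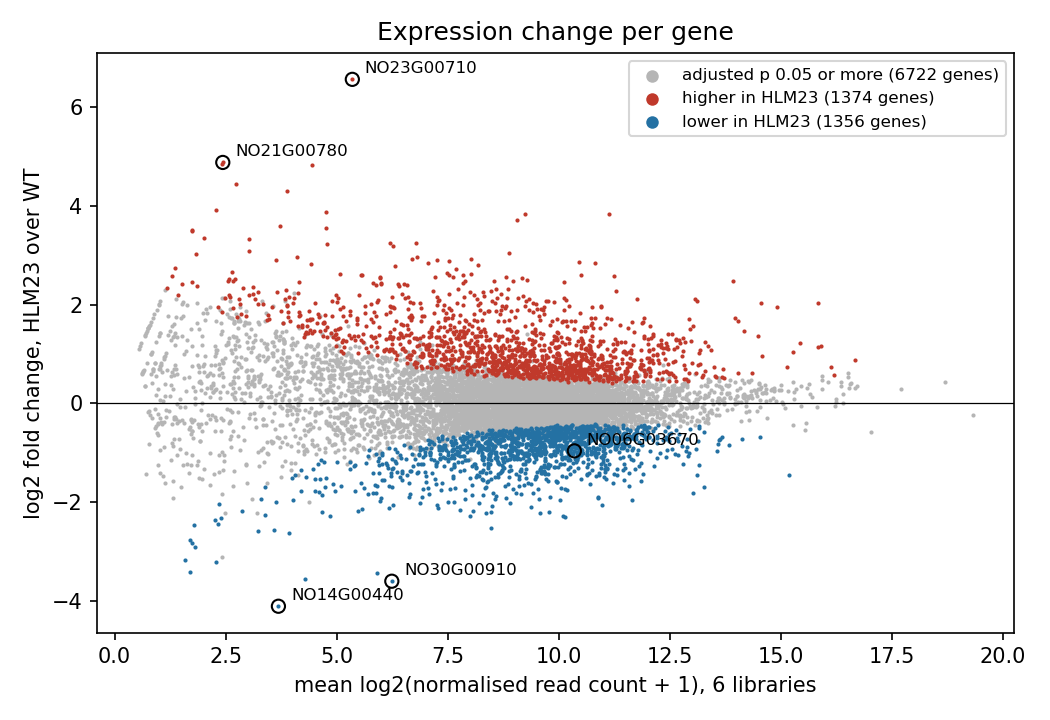
Each point is 1 of 9452 tested genes, with its mean log2(normalised read count + 1) over 6 libraries on the x axis and its log2 fold change of HLM23 over the WT on the y axis. Coloured points passed an adjusted p of 0.05 (1374 higher, 1356 lower), and circles mark NO06G03670 and the 4 other named genes.

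The deposited table gives gene IDs without descriptions, and none of its 9552 IDs matched the reference table of 160 organelle genes, so functions are not assigned here and only 2 genes that rose and 2 that fell are named. Among genes that met the rule for naming, the largest fitted rise was that of NO23G00710 on the minus strand of chromosome 23 (266473 to 269815). It was close to silent in the WT, at 3.81 ± 3.20 normalised reads, and reached 428 ± 201 in HLM23 (SD, n = 3), 112 times the WT mean (log2 fold change 6.56 ± 0.49 SE, limma adjusted p = 6.2e-05). The ratio rests on a WT mean near 0, and without WT replicate 1 it was 218 (log2 fold change 7.06). NO21G00780 on the minus strand of chromosome 21 (263434 to 264284) was listed at 0 in all 3 WT libraries and at 21.7, 28.3 and 37.0 in HLM23 (limma adjusted p = 0.00049). No ratio to the WT is given for it, because the WT value is 0, and its fitted size depends on the pseudocount. With log2(value + 0.1) it ranked above NO23G00710, at a fitted log2 fold change of 8.15 against 6.95.

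The deepest fitted fall under the same rule was that of NO14G00440 on the minus strand of chromosome 14 (172006 to 174641). Its normalised read count was 61.2 ± 42.2 in the WT and 3.17 ± 3.26 in HLM23 (SD, n = 3), a fall to 5.18% of the WT mean (log2 fold change -4.11 ± 0.74 SE, limma adjusted p = 0.0022). Without HLM23 replicate 2, in which it was listed at 0, the log2 fold change was -3.29, without HLM23 replicate 1 it was -4.74, and without WT replicate 3 it was -3.59. NO30G00910 on the minus strand of chromosome 30 (337274 to 339430) was steadier, at 264 ± 27.6 in the WT and 23.1 ± 12.6 in HLM23 (SD, n = 3), or 8.76% of the WT mean (log2 fold change -3.60 ± 0.38 SE, limma adjusted p = 0.00035). The strains did not overlap in any of these 4 genes, which the rule for naming them required, and all 4 stayed past the threshold in each alternative run. The pseudocount sets the fitted size where a strain is near 0: with log2(value + 10) the log2 fold change of NO23G00710 was 4.90 and that of NO14G00440 was -2.30. The order of NO14G00440 and NO30G00910 was not stable. NO30G00910 showed the deeper fitted fall with log2(value + 10) (-3.12), without HLM23 replicate 2 (-3.65) and without WT replicate 3 (-3.65).

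**Figure D2:**
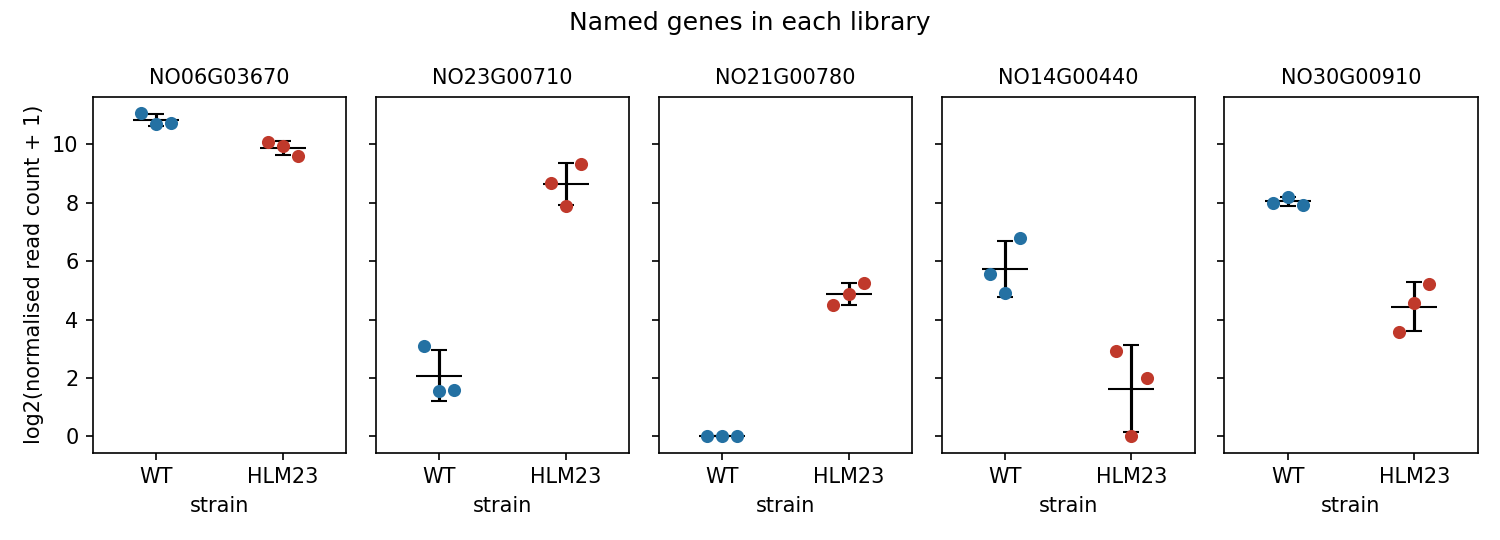
Points give log2(normalised read count + 1) in each library of the WT (blue) and HLM23 (red) for the disrupted gene and the 4 other named genes, and the bars show the mean ± SD of 3 libraries. The strains are separate in all 5 panels, and NO06G03670 shows the smallest difference of the 5 (log2 fold change -0.96).

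An inserted cassette can also change the genes beside it, so the 10 nearest genes on each side of NO06G03670 were compared. Of these 20 genes, between 977021 and 1049053 on chromosome 6, 4 differed between the strains, both over all genes tested and adjusted over the list alone, with 2 higher and 2 lower in HLM23. The gene at 993522 to 997455, which lies 7062 bases from NO06G03670, rose from 175 ± 45.4 to 506 ± 146 normalised reads (SD, n = 3, log2 fold change 1.52 ± 0.26 SE, limma adjusted p = 0.0018). On the other side, the gene at 1016332 to 1023376 fell by 0.75 on the log2 scale (limma adjusted p = 0.014). The gene at 1030325 to 1032704 fell by 1.04 (limma adjusted p = 0.029), and the gene at 1047728 to 1049053 rose by 0.84 (limma adjusted p = 0.019). The genes directly beside NO06G03670 did not pass the threshold, with log2 fold changes of 0.36 (limma adjusted p = 0.23) for the gene at 1002117 to 1004317 and 0.60 (limma adjusted p = 0.096) for the gene at 1015542 to 1015796. The share of neighbours called, 20.0%, was not distinguishable from the 28.9% of all tested genes (2-sided Fisher's exact test, p = 0.47). Without HLM23 replicate 3 or without WT replicate 1, 2 of the 20 genes were called.

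**Figure D3:**
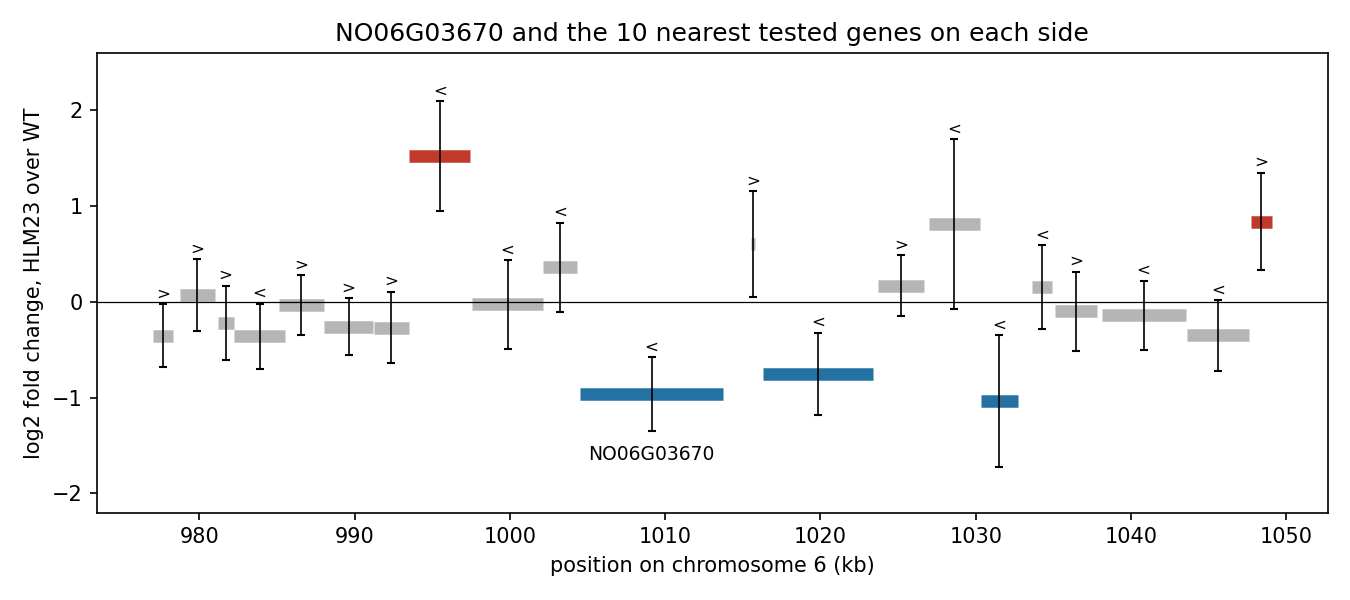
The x axis is the position on chromosome 6 in kb and the y axis the log2 fold change of HLM23 over the WT, with each bar spanning a gene and the lines giving 95% confidence intervals. Red and blue mark genes past an adjusted p of 0.05, arrowheads give the strand, and the changed genes, at 1.52, -0.75, -1.04 and 0.84, are interspersed with genes that did not pass the threshold.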

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

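The larger pseudocount, the removal of a length trend and the fit without both replicate 2 libraries were chosen after the data were seen. NO06G03670 and the 4 other named genes kept their direction and their side of the threshold in all 80 values computed for them, 16 per gene. The log2 fold change of NO06G03670 ranged from -1.07 with equal library totals to -0.77 with the length trend removed, and its adjusted p from 1.7e-05 in the authors' deposited table to 0.017 without WT replicate 1. The number of genes past the threshold was 2730 as reported and 1303 at an adjusted p under 0.01. Leaving out 1 library, which leaves fewer samples to test, gave 1527 to 2655 genes, with 858 to 1327 higher and 669 to 1340 lower, and the genes called beside NO06G03670 numbered 2 to 4. Leaving out both replicate 2 libraries gave 2250 calls, of which 2108 were among the calls reported, and 1591 genes changed at least 2-fold against 1219 reported. With the replicate block the count was 2635, of which 2508 were among the calls reported, and no named gene changed its call. The numbers were not shown to pair the samples, and no label ties a number to a day or batch. Correlations of deviations from the strain means were -0.07, -0.11 and 0.15 for numbers 1, 2 and 3. By that measure, of the 6 libraries only replicate 3 of each strain correlated best with its own number. Shifts in opposite directions tend to give negative values by that measure, so they do not count as a match. The replicate 2 libraries, at -0.11, shifted in opposite directions, and their Spearman correlation of 0.976 was the highest between the strains. Pairing by number therefore stays open. Equal library totals gave 2627 calls, 39.0% of them higher against 50.3%, with 2376 shared. The remaining alternatives gave between 2663 and 3025 calls. The planned count models (edgeR with either scaling, DESeq2) and set tests were not run, the first for the reason given under processing and the second for want of gene descriptions. Depth limits the genes with few reads: a gene listed at 0 may be present below a few reads, and the fitted log2 change of NO21G00780 was 8.15 with a pseudocount of 0.1 and 1.94 with 10.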

Other observations

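The tests of pair distance and orientation, of tandem pairs, of adjacency, of the chromosome 30 reads and of both explanations for the replicate 2 libraries were chosen after the results were seen, as were the regions and genes singled out. Some large changes lay next to each other along the chromosomes, while over all genes the rank correlation of fold changes was 0.0091, 0.011 and 0.010 between genes 2, 3 and 10 places apart. In 24 places, 3 or more consecutive tested genes changed at least 2-fold in the same direction (10 higher, 14 lower in HLM23), against a median of 5 and at most 13 in 1000 shuffles of the gene order. The deepest was a stretch of 3 genes on chromosome 30 from 329754 to 342510, which includes NO30G00910. The first gene (329754 to 332264) was listed at 0 in all HLM23 libraries and at 19.7, 4.79 and 9.08 in the WT. The other gene beside NO30G00910 (339466 to 342510) stood at 20.6 ± 15.9 in HLM23 and 200.4 ± 47.8 in the WT (SD, n = 3). The genes flanking the stretch did not pass the threshold, with log2 fold changes of -0.19 and -0.31. On chromosome 10, 3 short genes between 666709 and 669791 on the same strand were lower in HLM23, at low levels: the first was listed at 0 in all HLM23 libraries and at 14.1, 3.83 and 9.08 in the WT, and the others stood at 1.66 ± 2.01 against 12.4 ± 7.69 and 5.27 ± 4.94 against 30.1 ± 13.9 (SD, n = 3). On chromosome 21, NO21G00780 and the next gene (266354 to 268096) were both near 0 in the WT and detected in every HLM23 library.

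Some genes were near silent in 1 strain and detected in the other. With a mean of at least 10 in 1 strain and under 1 in the other, 8 genes were on in HLM23, all 8 past the threshold, and 3 were on in the WT, 2 of them past it. Among the 8, on chromosomes 1, 6, 18, 21, 23 and 30, were the genes at 155 to 2780 on chromosome 6, with 2.17, 7.80 and 51.0 normalised reads, and at 578 to 4958 on chromosome 30, with 2.17, 15.6 and 19.0. Among the fifth of genes with the lowest abundance, 292 were higher and 143 lower. In the fifth with the longest genes (3261 bases or more), 258 were higher and 395 lower, with a median log2 fold change of -0.13. With a length trend removed from each library, which centres these genes by construction, they held 336 higher and 312 lower, with a median of -0.024. A gene on chromosome 5 (557321 to 558089) reached 282 in HLM23 replicate 3 and 709 in WT replicate 2 and lay at or below 7.60 in the other 4 libraries, and it is the only gene with a blank p in the authors' deposited table.

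The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The split by strain gave 2730 genes in limma, 1 of 10 splits with as many, and the highest of the others gave 0, with at most 500 at an unadjusted p under 0.05. Every other split mixes the strains, which adds the strain difference to the spread within its groups. Low counts there were nearly fixed in advance and lend no support.

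Adjacent genes changed together where they were divergent or in tandem. The rank correlation of their fold changes was 0.171 across 2871 divergent pairs and 0.167 across 3682 tandem pairs, each above its shuffled range (-0.036 to 0.036 and -0.030 to 0.033), and -0.00070 across 2869 convergent pairs. Divergent minus convergent was 0.172 (1-sided permutation p = 0.0001, the smallest that 10000 permutations can give), though pairs of genes are not independent replicates. Reads shared between adjacent genes are argued against as the whole cause in divergent pairs, which gave 0.111 at least 500 bases apart (shuffled upper bound 0.070), but stay open in tandem pairs, which gave 0.240 under 500 bases without overlap and 0.0498, within the shuffled range, at least 500 bases apart. Co-variation not tied to the strain stays open for both. Neighbours also varied together between libraries of the same strain, with mean rank correlations over 4 such contrasts of 0.0891 in divergent and 0.116 in tandem pairs. All 4 contrasts include a replicate 2 library, and these lay between the strains. The contrasts can therefore carry part of the strain difference and cannot show that the co-variation is independent of it. In tandem pairs the values met the bounds set for shared reads and for co-variation within strains. Both bounds were written after the results, so meeting them is not a prediction borne out. The value of 0.0498 met its bound by a narrow margin and lay just under the upper end of its shuffled range, 0.0514. No biological explanation was tested.

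Among adjacent genes with large changes, 147 adjacent pairs changed at least 2-fold in the same direction, above the highest of 10000 shuffles (119), which argues against chance adjacency, and without the replicate 2 libraries the count was 242 against at most 177. Pairs that do not overlap gave 132, against at most 109 in shuffles, so overlapping annotation does not account for all of them. Loss of the chromosome 30 region from the HLM23 genome stays open. NO30G00910 kept at least 10.9 normalised reads in every HLM23 library, more than a complete loss alone would leave. The possible sources of these reads, such as near-identical copies or RNA of the WT, were not told apart. No genome was used here to search for such copies. No biological explanation was tested, as function and sequence were not analysed here.

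The replicate 2 libraries lay between the strains. Over 1591 genes changed at least 2-fold in the other 4 libraries, HLM23 replicate 2 stood 23.1% and WT replicate 2 29.6% of the way to the other strain. The genes and both strain means come from the same 4 libraries, and choosing genes for a large difference there tends to raise these values. The same measure was -21.1% and -15.6% for replicate 1 (572 genes) and 13.1% and -5.48% for replicate 3 (862 genes), each over genes chosen without those libraries. The strain means behind the values of replicates 1 and 3 include the replicate 2 libraries, which tends to lower those values. They are therefore not an independent baseline. Exchanged labels are argued against by the last of 4 gene sets tried, in which 11.1% of 253 genes lay nearer to the other strain (exact 95% interval 7.48% to 15.6%, below the 50% an exchange would exceed). The interval treats genes as independent, which genes of the same library are not, so it does not measure how certain the labels are. The bound of 50% was set after these results, in place of a first bound of 5% that no set met: the sets before it gave 2 of 3 genes, which decides nothing, 20.8% of 48 and 11.7% of 256. RNA of the other strain stays open. It needs 1 share at any fold, and the medians did not meet this. In WT replicate 2 the median share was 29.6% over genes changed at least 2-fold and 17.1% over the last set. In HLM23 replicate 2 it was 23.1% and 9.20%. The 90th percentiles of the last set, 31.8% and 28.1%, still lay above the 2-fold medians. The sets are also unlike, as the last holds only genes higher in the other strain and the 1591 genes run in both directions. In the second set the median share was 16.0% over 43 genes in WT replicate 2 and -0.45% over 5 in HLM23 replicate 2. Genes at a mean under 1 in their own strain and at least 10 in the other, a set chosen later still, did not settle it. In WT replicate 2, 16 such genes stood at a median of 3.20% of the HLM23 level (range 0% to 490%, 8 listed at 0), below the 17.1% share. In HLM23 replicate 2, 6 stood at a median of 8.90% of the WT level (range 0% to 89.2%, 2 listed at 0), close to the 9.20% share. These genes lie near the floor and spread widely, and a difference in growth state between cultures was not tested.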
